A study of Homo sapiens with 8 samples.

How the data were processed

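RNA from T47D cells, an established estrogen receptor-positive luminal breast cancer line, was measured on 8 Affymetrix Human Gene 1.0 ST arrays, which read whole transcripts through sets of short probes. Per the labels' protocols, cells were kept in steroid-deprived medium for 2 days before transfection with 200 nM siRNA. The siRNA was a scrambled control or a pool of 3 siRNAs against 17β-HSD1, the enzyme encoded by HSD17B1 that reduces estrone to estradiol. After 48 h the cells received 1 nM estradiol (E2) or ethanol vehicle for 2 days. Total RNA with an integrity number above 8 was amplified from 0.2 µg, and 2.7 µg of labelled cDNA was hybridised, per the labels. Each of the 4 groups had 2 arrays, from 2 independent cell culture experiments.

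The deposited table holds 33297 probe sets on a log2 scale, which was read from the values (2.42 to 15.2). The summarisation, background correction and normalization that the authors used are not given in the sources used here, and the scanner files were not used here. Array medians lay between 7.25 and 7.37. Quartiles were close between arrays but the distributions were not identical, so values were tested as deposited. The number of arrays limits the precision: with 2 per group the fit had 4 residual degrees of freedom per probe set.

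Probe sets were named through the platform annotation, with symbols checked by gene identifier against the RefSeq table of GRCh38.p14, used for names only. There were 19460 probe sets with 1 symbol, 1754 with several and 12083 with none, and the 21214 with at least 1 symbol were tested. No gene was named from a probe set with several symbols. Where a gene had several probe sets, the 1 with the highest mean over the arrays stood for it, which left 18417 genes. No coordinates are given, because no genome build is stated for the table.

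Tests used limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group over all 8 arrays, then eBayes). The 7 contrasts were the knockdown in vehicle, the knockdown in E2, the E2 effect with each siRNA, their difference (the interaction), and the knockdown and E2 effects averaged over the levels of the other factor. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05. Changes are log2 differences ± SE from the fit, averaged contrasts set 4 arrays against 4, and folds are 2 to that power. Gene groups were 18 lists: estrogen-induced, estrogen-repressed, cell cycle, replication-dependent histone, sex steroid metabolism, steroid receptor and coregulator, androgen-responsive, interferon and double-stranded RNA response, cholesterol synthesis, unfolded protein and amino acid stress, apoptosis, hypoxia and glycolysis, and adhesion and epithelial-mesenchymal genes, and markers of luminal, basal and myoepithelial, fibroblast, immune and endothelial cells. Of their 462 entries, 421 matched a gene. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 18 lists, and again with an estimated correlation.

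The groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule names HSD17B1, up to 12 genes per direction in each averaged contrast and up to 6 in the others, by size of change among called genes whose arrays do not overlap, filled to 4 by the smallest p as values only. It also names up to 4 members per list with the smallest p in each averaged contrast, and allows any called list member to be named.

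The labels say that the replicates came from 2 independent cell culture experiments and number them 1 and 2, so the number was taken as the experiment. Deviations from the group means of same-numbered arrays correlated at 0.44, 0.31, 0.31 and 0.42 for 4 of the 6 pairs of groups. For the control siRNA, vehicle group the correlation was 0.01 with the 17β-HSD1 siRNA, E2 group and -0.20 with the 17β-HSD1 siRNA, vehicle group. The fit with the number as a block is given beside a result where it changes a call or moves a count of calls by over 1.5 times.

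The procedure was tested on simulated data with the real means and spreads. Its noise was independent between probe sets and arrays, with the same spread in every group and no replicate effect. In the real arrays the SD of the difference between replicates ran from 0.20 to 0.38 by group. The rates that follow may therefore not hold for the real arrays. For the averaged knockdown over 21214 probe sets it called 100% of those changed by 1 and 66% of those changed by 0.5 on the log2 scale, with 16 false calls among 199. For the knockdown in vehicle it called 90% and 6%, with 13 false calls among 161. Alternatives were a filter on dim probe sets, all probe sets, a further quantile normalization, a trended robust spread model, the replicate block, fits on the 4 arrays compared, an additive model, leaving out each array, a fold threshold, and for lists fry, estimated correlation and means over probe sets. One probe set per gene and a crossed block were added after seeing the data. Figures were drawn with matplotlib 3.10.9.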

Results

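The arrays measured the transcriptome of T47D cells in 4 groups of 2 arrays: control siRNA with vehicle, control siRNA with E2, 17β-HSD1 siRNA with vehicle, and 17β-HSD1 siRNA with E2. The design asks what lowering 17β-HSD1 changes with and without added estradiol, and whether it alters the response of estrogen-regulated genes. Replicate 1 of 17β-HSD1 siRNA with vehicle stood apart from the rest. Its mean correlation with the other arrays was 0.973, against 0.981 to 0.988 for the others, and it lay at 40.1 on the first principal component, which held 38.2% of the variance.

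HSD17B1, the targeted gene, was lower in each of the 4 knockdown arrays than in each of the 4 control siRNA arrays, but the difference did not pass the threshold. With control siRNA its signal was 9.35 and 8.66 in vehicle and 9.12 and 8.56 in E2. With 17β-HSD1 siRNA it was 8.41 and 8.36 in vehicle and 8.32 and 8.37 in E2. The averaged change was -0.56 ± 0.16 (SE, 4 arrays against 4), 0.680-fold, with a limma adjusted p of 0.221. The change was -0.62 ± 0.23 in vehicle and -0.49 ± 0.23 in E2, with adjusted p of 0.812 and 1. The gap between the 2 control arrays in vehicle was about as large as the change itself. E2 changed HSD17B1 by -0.10 ± 0.16 on average (adjusted p = 0.987).

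**Figure D1:**
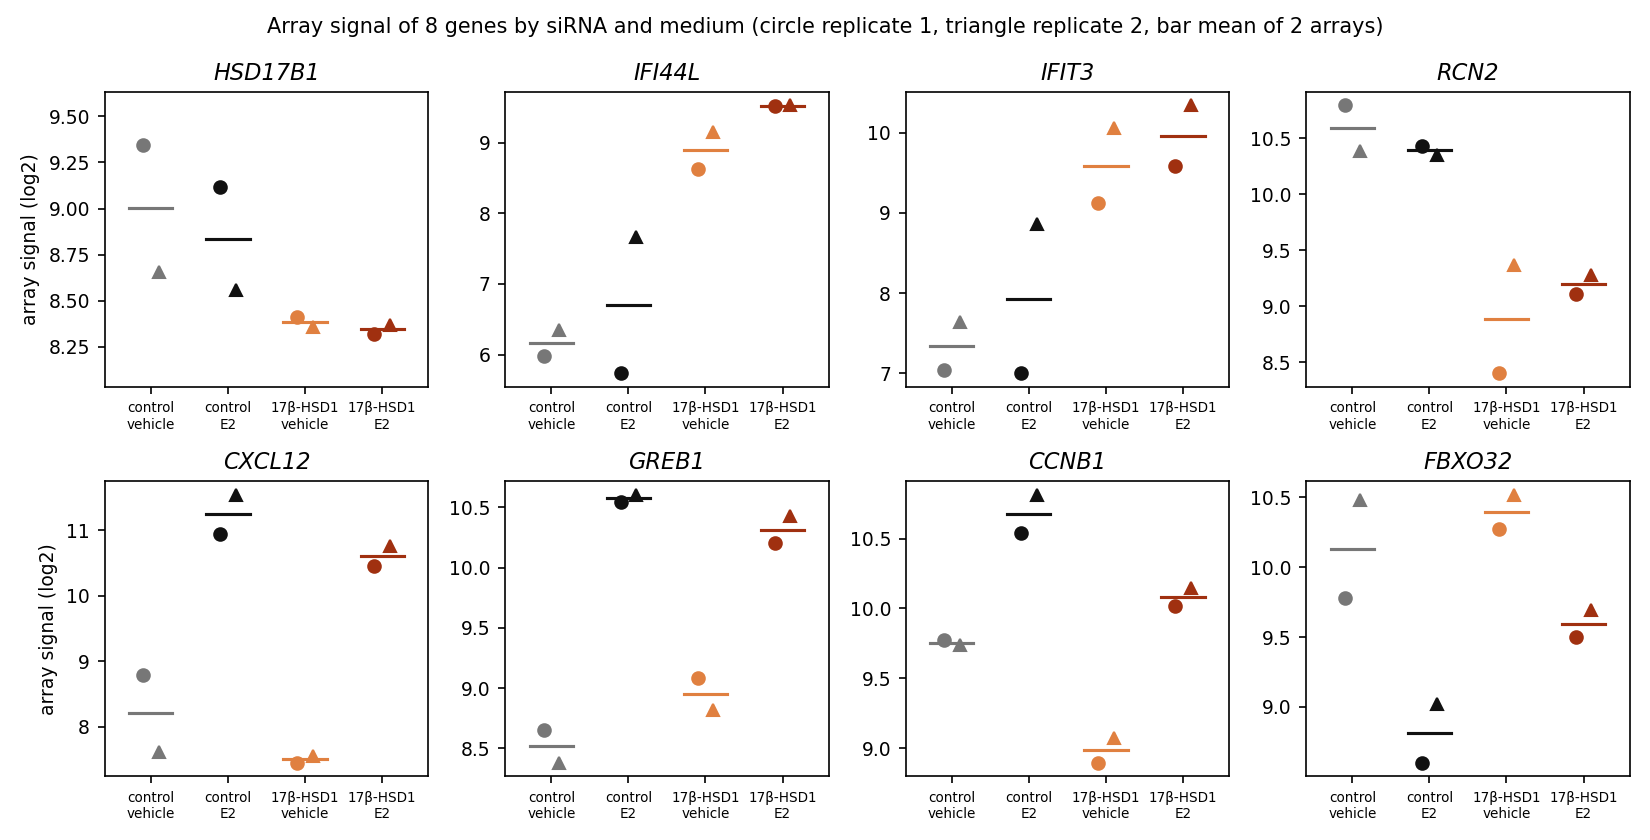
Array signal (log2) of 8 genes in the 4 groups, with circles for replicate 1, triangles for replicate 2 and bars for the mean of 2 arrays; each panel has its own range. HSD17B1 lies at 8.32 to 8.41 in the 4 knockdown arrays and at 8.56 to 9.35 in the 4 control siRNA arrays, IFI44L and IFIT3 are higher with 17β-HSD1 siRNA in both media, and CXCL12 and GREB1 are higher with E2 under both siRNAs.

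Averaged over the media, 17β-HSD1 siRNA raised antiviral and interferon-stimulated genes. IFI44L rose 6.84-fold (log2 change 2.77 ± 0.32, adjusted p = 0.0104), IFIT3 4.41-fold (2.14 ± 0.36) and RSAD2, which encodes the antiviral protein viperin, 3.93-fold (1.97 ± 0.33). The chemokine gene CCL5 rose 3.30-fold and XAF1 3.07-fold. The butyrophilin genes BTN3A2, BTN3A1 and BTN3A3, whose products are recognised by γδ T cells, rose 3.01-, 2.63- and 2.57-fold. TRANK1 rose 2.91-fold, HCP5, a non-coding RNA gene of the major histocompatibility region, 2.84-fold, OASL 2.71-fold and PLAAT4 2.61-fold. Among the falls, RCN2, a calcium-binding protein gene of the endoplasmic reticulum, dropped to 0.366-fold (-1.45 ± 0.19, adjusted p = 0.0104). HIPK3, a protein kinase gene, fell to 0.453-fold, CHUK, which encodes the IκB kinase α subunit, to 0.483-fold, AHNAK2 to 0.485-fold and GSKIP to 0.487-fold. POLE3 fell to 0.523-fold, BZW1 to 0.529-fold, TP53I3 to 0.530-fold, RNF11 to 0.542-fold and ESCO2, needed for sister chromatid cohesion, to 0.558-fold. The histone H3.3 gene H3-3B fell to 0.428-fold and its near-identical copy H3-5 to 0.448-fold, which the probe sets may not tell apart. All of these have adjusted p between 0.0104 and 0.0478 by limma, over 4 arrays against 4.

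In this averaged contrast 51 probe sets rose and 46 fell, of which 38 and 44 were single genes. With the replicate block 154 rose and 131 fell. No probe set was called when either 17β-HSD1 siRNA, E2 array was left out, or when the 12083 probe sets without a symbol were added to the fit. The total was 29 without control siRNA, vehicle replicate 1. The balance of directions also hung on single arrays, with 113 up and 27 down without control siRNA, E2 replicate 2, and 41 up and 145 down without 17β-HSD1 siRNA, vehicle replicate 2.

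Of the 29 measured interferon and double-stranded RNA response genes, all had positive averaged changes, with a median of 1.09. 8 rose (28 adjusted over the list alone, 24 with the replicate block): IFI44L, IFIT3, RSAD2, XAF1, OASL, IFITM1 (1.31 ± 0.17), IFI27 (0.99 ± 0.18) and TLR3 (0.84 ± 0.15), the receptor for double-stranded RNA in endosomes. The list's camera adjusted p was 3.84e-41, and the adjusted p was 0.156 with an estimated correlation. Its median was 1.14 in vehicle and 1.06 in E2, where it was 0.45 without control siRNA, E2 replicate 1 and 1.62 without replicate 2. The control arrays were not uniform for these genes: IFI44L had a signal of 7.67 in control siRNA, E2 replicate 2 and 5.73 in replicate 1.

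All 46 measured cell cycle genes had negative averaged changes, with a median of -0.49, and 8 fell (39 adjusted over the list alone, 17 with the replicate block). KIF20A changed by -0.76 ± 0.13, CDC6, which loads the replicative helicase, by -0.75 ± 0.12, TYMS by -0.73 ± 0.13, CCNA2 by -0.71 ± 0.12, the mitotic cyclin gene CCNB1 by -0.68 ± 0.11, KIF23 by -0.66 ± 0.10, MELK by -0.66 ± 0.11 and CDC20 by -0.57 ± 0.11. Camera's adjusted p was 8.59e-44, and the adjusted p was 0.156 with an estimated correlation. The median was -0.55 in vehicle and -0.44 in E2, or -0.24 in E2 without control siRNA, E2 replicate 2. Replication-dependent histone genes, expressed in S phase, had a median of -0.26, and 3 of 42 fell (18 adjusted over the list alone, 8 with the replicate block): H4C3 (-0.60 ± 0.11), H4C4 (-0.74 ± 0.14) and H4C2 (-0.56 ± 0.10). Camera gave an adjusted p of 3.58e-16, and the adjusted p was 0.156 with an estimated correlation. Histone genes are close copies, so their probe sets may share signal.

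None of the 39 estrogen-induced genes passed singly, also when adjusted over the list alone, and the list's median was -0.14 (camera adjusted p = 9.96e-05, adjusted p = 0.186 with an estimated correlation), -0.04 in vehicle and -0.26 in E2. MYBL1 changed by -0.64 ± 0.16, CXCL12 by -0.67 ± 0.22, HSPB8 by -0.68 ± 0.23 and RAB31 by -0.41 ± 0.12, with adjusted p between 0.147 and 0.307. None of the 22 estrogen-repressed genes passed (6 adjusted over the list alone, 3 with the replicate block), with a median of 0.18 (camera adjusted p = 7.26e-05, adjusted p = 0.156 with an estimated correlation), 0.05 in vehicle and 0.28 in E2. BLNK changed by 0.52 ± 0.11 and ARRDC3 by 0.56 ± 0.16. The hypoxia and glycolysis list had a median of -0.13 (camera adjusted p = 0.0303, adjusted p = 0.568 with an estimated correlation), with no member past the threshold. Without 17β-HSD1 siRNA, vehicle replicate 1 its camera adjusted p was 0.336.

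The other 12 lists did not pass in the averaged knockdown. Cholesterol synthesis genes had a median of -0.14 (adjusted p = 0.0507, or 0.028 with the replicate block). Sex steroid metabolism genes, which include HSD17B1, had a median of 0.02 (adjusted p = 0.419) and steroid receptor and coregulator genes 0.05 (0.215), with ESR1, the estrogen receptor α gene, at -0.32 ± 0.13. Medians were 0.02 for androgen-responsive (adjusted p = 0.505), 0.02 for unfolded protein and amino acid stress (0.733, or 0.0364 and up without 17β-HSD1 siRNA, vehicle replicate 1), -0.01 for apoptosis (0.946) and 0.00 for adhesion and epithelial-mesenchymal genes (0.994). Luminal epithelial markers had a median of -0.05 (0.889). Markers of other cell types had medians of 0.07 for basal and myoepithelial cells (0.105), 0.05 for fibroblasts (0.59), 0.02 for immune cells (0.505) and -0.01 for endothelial cells (0.889). Under the replicate block 1 androgen-responsive and 1 hypoxia gene rose, 1 cholesterol synthesis gene fell, and 1 adhesion gene rose and 1 fell.

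Within a single medium, no knockdown difference passed the threshold. In vehicle, IFI44L was 2.73 ± 0.45 higher on the log2 scale, IFITM1 1.34 ± 0.24, the secreted glycoprotein gene LGALS3BP 1.18 ± 0.20 and TIAM1 0.89 ± 0.15. RCN2 differed by -1.71 ± 0.26, HIPK3 by -1.20 ± 0.20, the tubulin gene TUBA1A by -0.97 ± 0.16 and the kinetochore gene NUF2 by -0.92 ± 0.15. Each had a limma adjusted p of 0.181, the lowest, and 1157 probe sets had an unadjusted p below 0.05, against 1061 by chance. With the replicate block 31 rose and 6 fell, but 0 were called when the numbers of the control siRNA, vehicle arrays were crossed in the block. In E2, IFI44L differed by 2.82 ± 0.45, AKAP6, a kinase anchoring protein gene, by 1.41 ± 0.21, IFITM3 by 1.40 ± 0.23 and the laminin gene LAMC1 by 1.01 ± 0.17. AHNAK2 differed by -1.13 ± 0.19, CHUK by -1.07 ± 0.19, POLE3, a subunit gene of DNA polymerase ε, by -1.06 ± 0.16 and RNF11 by -0.87 ± 0.16. The lowest adjusted p was 0.225, 977 probe sets had an unadjusted p below 0.05, and with the block 41 rose and 4 fell. Fits on the 4 arrays compared called 63 probe sets in vehicle and 1 in E2. The count in vehicle was 30 without either control siRNA, E2 array, and in E2 it was 65 without control siRNA, E2 replicate 2.

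**Figure D2:**
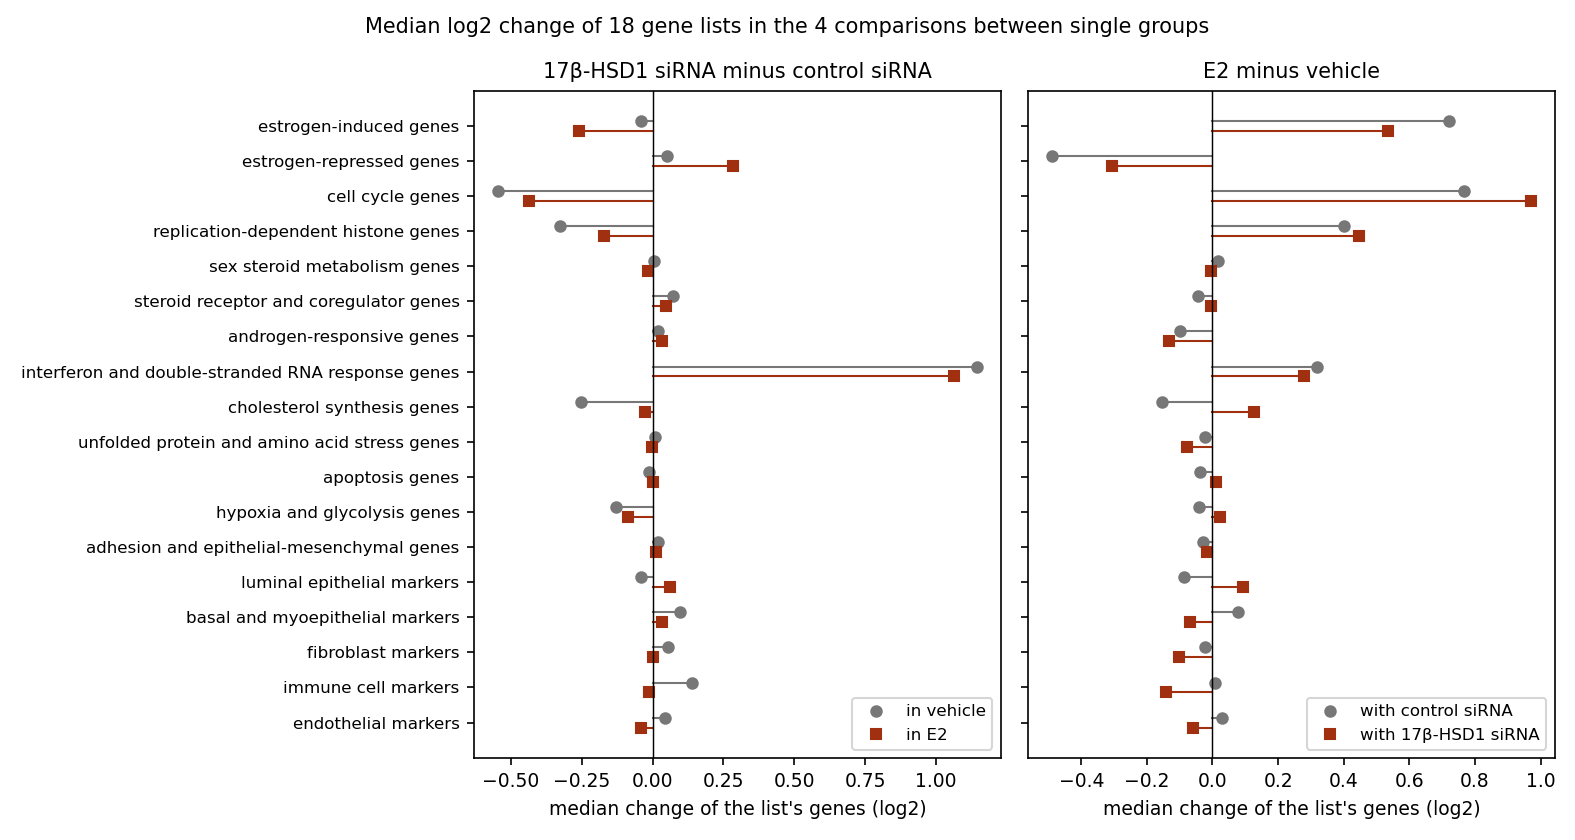
Median log2 change of the members of 18 gene lists, for 17β-HSD1 siRNA minus control siRNA in vehicle (circles) and in E2 (squares) on the left, and for E2 minus vehicle with each siRNA on the right. The interferon list stands at 1.14 and 1.06 on the left, the cell cycle list at -0.55 and -0.44 on the left and at 0.77 and 0.97 on the right.

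E2, averaged over the siRNAs, raised known estrogen targets. The chemokine gene CXCL12 rose 8.41-fold (3.07 ± 0.22, adjusted p = 0.000249), the transcription factor gene MYBL1 3.59-fold (1.85 ± 0.16) and GREB1, a receptor cofactor gene induced by estrogen, 3.28-fold (1.71 ± 0.12). PXK rose 3.12-fold, SERPINA6, which encodes corticosteroid-binding globulin, 2.99-fold, RBM24 2.92-fold, SEMA6A 2.91-fold and KCTD6 2.75-fold. The mitotic kinase gene PBK rose 2.57-fold, the neuropeptide Y receptor gene NPY1R 2.39-fold, the potassium channel gene KCNH1 2.36-fold and RAPGEFL1 2.33-fold. FBXO32, a ubiquitin ligase subunit gene, fell most, to 0.480-fold (-1.06 ± 0.16, adjusted p = 0.00787). FSIP2 fell to 0.512-fold, AKAP6 to 0.516-fold, BAMBI, a decoy receptor gene of TGF-β signalling, to 0.526-fold, and VTCN1, which encodes the immune checkpoint protein B7-H4, to 0.530-fold. LTBP1 fell to 0.536-fold, SOX2 to 0.545-fold, RHOBTB1 to 0.561-fold, BCAS1 to 0.572-fold, the hypoxia-inducible factor gene EPAS1 to 0.580-fold, ST6GAL1 to 0.585-fold and TCAF1 to 0.589-fold.

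The averaged E2 contrast called 281 probe sets up and 48 down, or 257 and 45 single genes, and 393 and 116 with the replicate block. The total was 99 when probe sets without a symbol were added to the fit, 137 and 121 without 17β-HSD1 siRNA, E2 replicates 1 and 2, and 197 without control siRNA, E2 replicate 2.

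Of the 39 estrogen-induced genes, 17 rose with E2 (29 adjusted over the list alone), with a median of 0.63. PGR, the progesterone receptor gene, rose by 1.04 ± 0.13, while TFF1 at 0.34 ± 0.18, CCND1 at 0.35 ± 0.14 and MYC at 1.17 ± 0.33, named after their values were seen, did not pass. Camera's adjusted p was 7.20e-44, and the adjusted p was 0.0138 with an estimated correlation. Of the 22 estrogen-repressed genes 8 fell (11 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 5.14e-15, adjusted p = 0.026 with an estimated correlation). They include EPAS1, the receptor tyrosine kinase gene ERBB2 (-0.72 ± 0.11), TP53INP1 (-0.70 ± 0.14) and CITED2 (-0.65 ± 0.12). Cell cycle genes rose in 38 of 46 cases (45 adjusted over the list alone), with a median of 0.90, among them PLK1 (1.18 ± 0.14), MKI67 (1.07 ± 0.13) and CCNB1 (1.01 ± 0.11). Of 42 replication-dependent histone genes, 17 rose (27 adjusted over the list alone), with a median of 0.42 and changes near 1 for H2BC14 (1.03 ± 0.12), H2AC4 (1.00 ± 0.11) and H3C2 (0.99 ± 0.11). Camera's adjusted p was 1.86e-83 for cell cycle and 4.51e-37 for histone genes, and the adjusted p was 0.026 for each with an estimated correlation.

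Androgen-responsive genes had a median E2 change of -0.12, and 1 of 21 fell, STEAP4 (-0.56 ± 0.12), also when adjusted over the list alone, and 3 with the replicate block (camera adjusted p = 0.000496, adjusted p = 0.0523 with an estimated correlation). Interferon genes had a median of 0.32 and no member passed, also when adjusted over the list alone (camera adjusted p = 0.000119, adjusted p = 0.933 with an estimated correlation). That call was lost without 17β-HSD1 siRNA, vehicle replicate 1 (adjusted p = 0.464), and the median was -0.03 without control siRNA, E2 replicate 2. In lists that did not pass, DDIT4 (-0.65 ± 0.13, adjusted p = 0.0347) and EGLN3 (-0.76 ± 0.14, adjusted p = 0.0234) fell singly. The unfolded protein and amino acid stress list had a median of -0.04 with all arrays (camera adjusted p = 0.599, adjusted p = 0.949 with an estimated correlation). It passed as lower without 17β-HSD1 siRNA, vehicle replicate 1. One gene each of the cholesterol synthesis, hypoxia and adhesion lists rose and 1 luminal marker fell under the replicate block. Medians of the 12 lists that did not pass lay between -0.08 for immune cell markers (adjusted p = 0.387) and 0.03 for sex steroid metabolism genes (adjusted p = 0.934).

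With control siRNA alone, E2 raised 15 probe sets and lowered 3. CXCL12 rose 8.22-fold (3.04 ± 0.32, adjusted p = 0.00776), GREB1 4.16-fold, RBM24 3.42-fold, MYBL1 3.29-fold, RAPGEFL1 2.86-fold and the RAS-like growth inhibitor gene RERG 2.43-fold. AKAP6 fell to 0.384-fold, FSIP2 to 0.417-fold and NBEA to 0.490-fold, with adjusted p of 0.0434, 0.0434 and 0.0458, and KLHL24 stood at -1.08 ± 0.17 (adjusted p = 0.0532). With the replicate block 89 rose and 38 fell, and only 1 probe set was called after a further quantile normalization and 0 in the fit of these 4 arrays. Counts were 2 without control siRNA, vehicle replicate 2, 6 without control siRNA, E2 replicate 2 and 5 without either 17β-HSD1 siRNA, E2 array.

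After 17β-HSD1 siRNA, E2 raised 57 probe sets and lowered 0. CXCL12 rose 8.61-fold (3.11 ± 0.32, adjusted p = 0.0113), MYBL1 3.92-fold, SERPINA6 3.90-fold, PXK 3.15-fold, the gastrin-releasing peptide receptor gene GRPR 2.81-fold and PBK 2.74-fold. Values for the lower side were -0.86 ± 0.15 for TIAM1, -0.81 ± 0.19 for BAMBI, -0.77 ± 0.15 for LIPK and -0.69 ± 0.17 for KCNJ13, with adjusted p between 0.0502 and 0.21. With the replicate block 108 rose and 3 fell, and 959 probe sets had an unadjusted p below 0.05. The count was 0 without any 1 of the 4 arrays compared, and 0 when probe sets without a symbol were added.

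The interaction, which tests whether the E2 response differed between the siRNAs, called 0 probe sets in limma with or without the replicate block. There were 140 with an unadjusted p below 0.05, against 1061 by chance. The p values thus ran higher than chance gives, for a cause not tested. The simulated data held no interaction, so the share of real interactions that would be called is not known. The 0 calls therefore do not show that the responses were alike. The smallest p values belonged to OR1F2P (-1.69 ± 0.33), LIPK (-0.87 ± 0.21), OR1S1 (-0.75 ± 0.21) and MOXD1 (-0.71 ± 0.20) on the lower side. On the upper side they belonged to TGFB2 (0.99 ± 0.26), ATRX (0.86 ± 0.24), RNU5E-1 (0.75 ± 0.21) and FAM86B3P (0.76 ± 0.25), each with an adjusted p of 1.

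As groups, estrogen-responsive genes were compared under knockdown. Of the 257 genes that E2 raised, 27 fell in the averaged knockdown, among them CCNB1, CDC6, CCNA2, KIF23, MELK, PBK and RBM24, where 0.614 would be shared by independent lists (two-sided Fisher's exact test, p = 1.12e-39). Of the 45 that E2 lowered, 2 rose, AKAP6 and TIAM1 (0.0928 by independent lists, exact p = 0.00388). The 27 include all 8 genes of the cell cycle list that fell, and the histone genes H4C3 and H4C4. The overlap thus restates in part the fall of cell cycle genes. In the fixed estrogen-induced list, 0 of 39 genes were called in the averaged knockdown. No gene was called in the same direction in both contrasts, and genes are not independent replicates. Both averaged contrasts use the same 8 arrays and share spread estimates. With the spread of each group, their estimated changes correlate by chance at -0.29, which favours shared genes in opposite directions. The 27 became 81 with the replicate block, 14 after a further quantile normalization, and between 0 and 54 when arrays were left out, with 0 without either 17β-HSD1 siRNA, E2 array.

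The E2-raised genes had a median knockdown change of -0.46 in vehicle and -0.39 in E2, with adjusted p of 0.0174 and 0.0139 by camera with an estimated correlation. Selection of this set used the same 8 arrays, and the chance correlation of -0.29 between the averaged contrasts favours such a fall. Those p values may therefore overstate it. The E2-raised genes had a median E2 change of 0.74 with control siRNA and 0.79 after 17β-HSD1 siRNA, and 91 of 257 had the smaller change after knockdown. Their median interaction was 0.06 (camera adjusted p = 0.0239, adjusted p = 0.568 with an estimated correlation). The E2-lowered genes had a median of -0.91 with control siRNA and -0.49 after knockdown, and 42 of 45 changed less after knockdown. Their median interaction was 0.38 (camera adjusted p = 3.72e-27, adjusted p = 0.0341 with an estimated correlation), and no single gene among them passed. These genes were chosen on the same arrays. Without 17β-HSD1 siRNA, vehicle replicate 1 the median interaction of the same genes was 0.29, and it was 0.09 over the 73 genes called as lowered without that array. Without replicate 2 of that group it was 0.59 for the same genes and 0.29 over the 26 called without it.

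**Figure D3:**
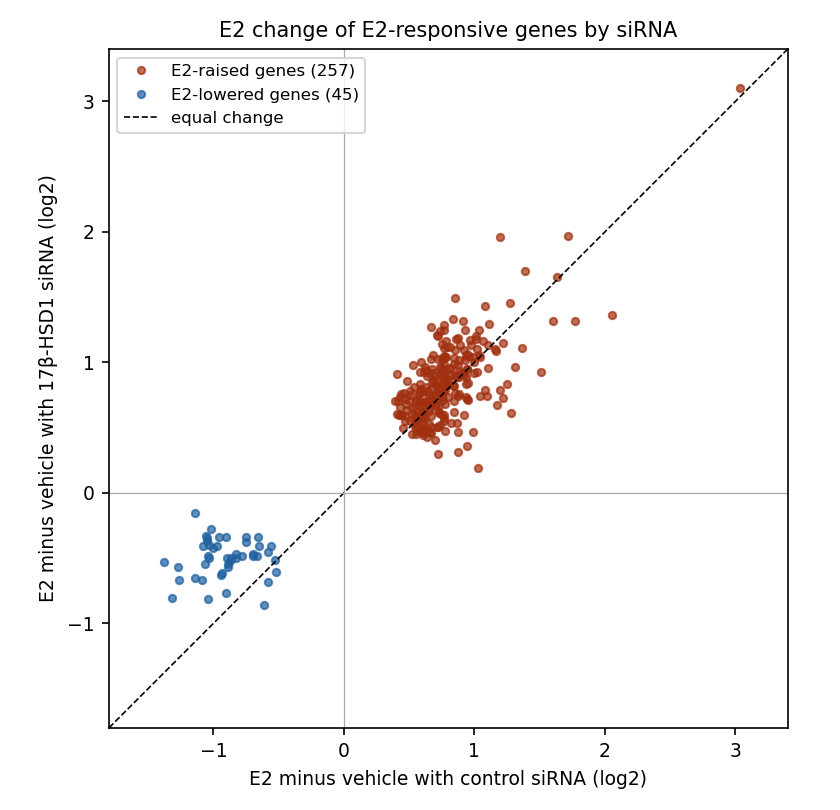
E2 minus vehicle (log2) with control siRNA on the horizontal axis and with 17β-HSD1 siRNA on the vertical axis, 1 point per gene, for the 257 E2-raised and 45 E2-lowered genes; the dashed line marks equal change. E2-raised genes lie on both sides of the line (medians 0.74 and 0.79), and 42 of the 45 E2-lowered genes lie nearer 0 on the vertical axis.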

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

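Apart from camera's tests of the fixed lists, the calls among probe sets without a symbol and the test of the siRNA pool, the tests below were chosen, bounded or narrowed after results were seen, and the single-array test of the E2-lowered genes was widened to genes chosen again after that value was known.

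The interferon list was 1.09 higher at the median with 17β-HSD1 siRNA. A single array does not account for it, since the median lay between 0.78 and 1.41 when each array was left out. Loss of estradiol formed by the enzyme predicts that E2 given after knockdown lowers the list by at least 0.57, but its median changed by 0.28 (-0.0919 to 0.54 without each array), which argues against a loss that E2 makes good within 2 days. The knockdown median in E2 was 0.932 of that in vehicle (0.391 to 1.42 without each array), a range too wide to decide. A response to the siRNA pool itself, rather than to the loss of 17β-HSD1, cannot be told apart from it, because 1 pool was compared with 1 control siRNA.

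The cell cycle list was 0.49 lower at the median, and -0.37 was the smallest fall when each array was left out, which argues against a single array. Lower estradiol action would bring down estrogen-induced genes in step. In vehicle the list's median was -0.0420 (-0.0420 to 0.0260 without each array), above the bound of -0.19, where -0.38 was predicted in full. The distance to the full prediction exceeded the members' SD (0.296) in only 7 of 9 fits, those without each array included. That SD is a spread between genes, not the error of the median. By this measure lower estradiol action stays open there. In E2 the median was -0.26, past the bound of -0.15 with all arrays and without each, so lower estradiol action may contribute there. Lower action only in E2 medium would, however, make the E2 change of cell cycle genes smaller after knockdown. Their median E2 change was 0.97 after knockdown and 0.77 with control siRNA. Their median interaction was 0.0905, but -0.0685 without control siRNA, E2 replicate 1, so these values do not decide it. A growth effect of the interferon response was not tested. For the cell cycle fall too, a response to the siRNA pool itself cannot be told apart from the loss of the enzyme. Only 1 pool was compared with the control siRNA.

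As a set, the E2-lowered genes differed between the siRNAs in their E2 response, with a median interaction of 0.38. They were chosen on the same arrays, and no single gene among them passed. For this difference too, a response to the siRNA pool itself cannot be told apart from the loss of 17β-HSD1. A lower starting level needs the E2-lowered genes lowered by knockdown in vehicle. Their median change there was 0.00965 (-0.10 to 0.19 without each array), above the bound of -0.19. The distance to the full -0.38 exceeded the members' SD (0.267), a spread between genes, in 8 of 9 fits, not all. By this measure a lower starting level stays open. A weaker estradiol response in general stays open, since 2 groups of genes go apart. The median E2 change after knockdown over that with control siRNA was 1.06 for E2-raised genes (0.920 to 1.28 without each array) and 0.740 for the estrogen-induced list (0.53 against 0.72, ratio 0.636 to 0.897 without each array), and the estrogen-repressed list had -0.31 against -0.49. Also open is a contribution of a single array, since the interaction was at least 0.29 for these genes without each array but 0.09 for genes chosen again without 17β-HSD1 siRNA, vehicle replicate 1.

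The fixed lists whose E2 response differed between the siRNAs by camera's interaction test had median interactions of -0.20 for estrogen-induced, 0.22 for estrogen-repressed, 0.0905 for cell cycle, 0.14 for replication-dependent histone and 0.22 for cholesterol synthesis genes and -0.12 for immune cell markers. Their adjusted p lay between 4.86e-06 and 0.00995, and with an estimated correlation the adjusted p was 0.252 for both estrogen lists and 0.678 for the others. The median interaction of the estrogen-induced list shrank to -0.0998 without control siRNA, vehicle replicate 2. Without 17β-HSD1 siRNA, vehicle replicate 1 the adjusted p was 0.22 for estrogen-repressed genes, 0.335 for cholesterol synthesis genes and 0.22 for immune cell markers. Without it the interferon list and the unfolded protein and amino acid stress list passed instead, with adjusted p of 1.22e-05 and 0.00333. With the replicate block luminal markers joined them (median 0.18, adjusted p = 0.0237). Without the block the camera adjusted p of luminal markers was 0.123, and the adjusted p was 0.665 with an estimated correlation. E2-raised genes had a median interaction of 0.0608.

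Among the 12083 probe sets without a symbol, 6 passed the threshold in the averaged E2 contrast and 0 in the other contrasts. All 6 were higher with E2, by 0.93 to 1.71 on the log2 scale.

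The 8 arrays can be parted 4 against 4 in 18 ways that keep the other factor even on both sides, too few for a share under 0.05. With the other factor in the fit but no interaction, the real knockdown split called 157 probe sets and the real E2 split 403. The highest other split called 0 in both cases, also among splits even for the replicate number. Those other splits leave the real effect in the residual spread, which hides calls, so their 0 does not argue against chance.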

How the results depend on the processing

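One probe set per gene and the crossed block were chosen after results were seen, and the cause of each change below was not tested unless given. HSD17B1 kept its direction and its side of the threshold with all probe sets, quantile normalization again, the trend and robust model, the replicate block and each array left out, from -0.38 to -0.73 without each array, with limma adjusted p from 0.0611 to 0.755. None of 63 calls of named genes reversed, and the block ended none of them. These genes were chosen for arrays that do not overlap, so leaving out an array could not reverse them. The other fits, apart from the further quantile normalization, keep the same log2 changes, so the lack of reversals among the calls shows little. Without 17β-HSD1 siRNA, E2 replicates 1 and 2, 40 and 43 were lost, and 50 were lost with all probe sets of the table. Probe sets without a symbol were more variable (median residual SD 0.201 against 0.164) and lowered the prior degrees of freedom from 7.20 to 4.34. With only that prior over the tested probe sets, the averaged knockdown called 0.

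With all probe sets of the table, 0 were called for the knockdown averaged, 99 for E2 averaged, 1 for E2 in control siRNA and 0 for E2 in 17β-HSD1 siRNA. With the replicate block, calls were 37 for the knockdown in vehicle, 45 for the knockdown in E2, 127 for E2 in control siRNA, 111 for E2 in 17β-HSD1 siRNA, 285 for the knockdown averaged and 509 for E2 averaged, and 81 for estradiol-responsive genes under knockdown. With the numbers of the control siRNA, vehicle arrays crossed, the knockdown in vehicle called 0. After quantile normalization again, calls were 1 for E2 in control siRNA, 30 for E2 in 17β-HSD1 siRNA, 62 for the knockdown averaged (36 up, 26 down) and 14 for estradiol-responsive genes under knockdown. The trend and robust spread model called 39 and 1 probe set per gene called 28 for E2 in control siRNA, and the additive model called 157 for the knockdown averaged. Fits on only the 4 arrays compared called 63 for the knockdown in vehicle, 1 for the knockdown in E2, 0 for E2 in control siRNA and 95 for E2 in 17β-HSD1 siRNA. At an unadjusted p below 0.05 and at least 1.5-fold, counts were 373 and 315 for the knockdown in vehicle and in E2, 484 and 379 for E2 in control siRNA and in 17β-HSD1 siRNA, 86 for the interaction and 293 for the knockdown averaged.

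Without each array in turn, counts ran from 0 to 30 for the knockdown in vehicle, 0 to 65 for the knockdown in E2, 2 to 26 for E2 in control siRNA, 0 to 79 for E2 in 17β-HSD1 siRNA, 0 to 186 for the knockdown averaged, 121 to 319 for E2 averaged and 0 to 54 for estradiol-responsive genes under knockdown. Lists passing in the interaction numbered 6, from 3 to 7 without each array and 0 by fry or with the correlation estimated. Lists passing in the knockdown averaged numbered 6, and 0 by fry or with the correlation estimated. Results that reversed without an array include the median interaction of E2-raised genes (0.0608 with all; over the genes called anew in each fit, -0.11 without control siRNA, E2 replicate 1, up to 0.18; over the 257 genes, -0.0684 without that array), that of cell cycle genes (-0.0685 without the same array, up to 0.32), that of immune cell markers (0.0866 without 17β-HSD1 siRNA, vehicle replicate 1, down to -0.39) and the interferon genes' E2 averaged median (-0.0277 without control siRNA, E2 replicate 2, up to 0.59). The interferon genes' E2 median with control siRNA was also -0.30 without that array, after knockdown it was -0.0919 without 17β-HSD1 siRNA, vehicle replicate 1, and E2-lowered genes had -0.10 for the knockdown in vehicle without replicate 2 of that group. Fits with 1 array left out take the spread of the lone array from the other groups. Probe sets near background may understate changes, and the dim filter left 90 calls for the knockdown averaged.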

Other observations

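Of 13 genes of antigen presentation by class I molecules, 4 rose with 17β-HSD1 siRNA; this group and the interferon and class II groups were chosen after their values were seen. PSMB9, an immunoproteasome subunit gene, rose by 1.23 ± 0.19 on the log2 scale in the averaged knockdown, the peptide transporter gene TAP1 by 1.09 ± 0.15, B2M, which encodes β2-microglobulin, by 0.94 ± 0.15 and the peptide-trimming enzyme gene ERAP1 by 0.94 ± 0.17, with limma adjusted p between 0.0138 and 0.0384. PSMB8 stood at 0.98 ± 0.22, ERAP2 at 0.96 ± 0.25, the class I transactivator gene NLRC5 at 0.41 ± 0.10, TAPBP at 0.16 ± 0.12, CALR at 0.50 ± 0.16, TAP2 at 0.34 ± 0.12, PSME1 at 0.20 ± 0.12, PSMB10 at 0.11 ± 0.11 and PSME2 at 0.03 ± 0.13 without passing. Over the 13 genes the median was 0.50, and over 8 class II genes 0.04. TAP1 and PSMB9 have identical probe sets on alternative haplotypes, counted here once.

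No interferon gene of 7 measured ones passed. IFNL2 changed by 0.64 ± 0.14, IFNL3 by 0.54 ± 0.14, IFNB1 by 0.53 ± 0.14 and IFNL1 by 0.47 ± 0.11, with adjusted p between 0.0881 and 0.165, while IFNA2 stood at -0.10 ± 0.16 and IFNK at 0.10 ± 0.13. IFNL2 and IFNL3 are near-identical copies, and IFNB1 had a mean signal of 5.54. The median over the 7 was 0.47.

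The fall of HSD17B1 was among the larger ones, with 152 of 18417 genes having a larger averaged fall. These include all 44 falls that passed the threshold, which are selected in part for size. The smallest of these 44 was -0.561, against -0.556 for HSD17B1. Of the 82 genes called in the averaged knockdown, 53 were not called in the averaged E2 contrast, 36 that rose and 17 that fell.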
